A study of Mus musculus with 24 samples.

How the data were processed

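Tcra cDNA libraries were made from splenic CD4 T cells purified by flow cytometry (positive for Vβ8 and CD4, negative for NK-1.1, CD8α and CD1d tetramer), with barcodes attached at reverse transcription, per the labels. The 2 lineages (Tconv and Treg) and 3 activation states, each with 4 replicates, make 24 libraries. Each deposited clone table lists a count and a fraction for every CDR3 nucleotide clonotype, with its V and J hits. The deposited counts are whole numbers, and the deposited fraction is the count divided by the library's total, which was checked on every table. Whether 1 count is 1 barcode or 1 read is not given in the sources used here, nor are the aligner, its version, the segment reference and the error correction. All clonotypes listed are in frame, and clone numbers skip 189 to 1052 entries per library.

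Every library was grouped as its label states. Counts were summed to TRAV genes and TRAJ genes by the top hit, and to amino acid clonotypes by TRAV family and CDR3 sequence. There were 99 TRAV names in 22 families and 44 TRAJ names. Positions of named segments come from the GENCODE vM21 annotation of GRCm38. The clone tables hold no genome positions.

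Segments and clonotypes were tested with edgeR 4.0.16 (quasi-likelihood fit, library totals as the scale) in R 4.3.3 with limma 3.58.1, fitting each of the 7 comparisons on its 8 libraries. Segments were tested if they passed edgeR's filterByExpr, and a clonotype if it had at least 1 count in at least 4 of the 8 libraries. The threshold was an adjusted p of 0.05. TMM factors, DESeq2 1.42.0 with its size factors, no filter on low counts, all 6 groups in 1 fit, merged D and N copies, each nucleotide clonotype counted once, a block on replicate number, CDR3 sequence without the TRAV family and every library left out in turn were the alternatives. Measures of whole repertoires were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. These measures were richness at 5952 counts (mean of 20 draws, and 2976 counts as an alternative), normalised Shannon entropy, CDR3 length, the makeup of the 5 central CDR3 residues (3 as an alternative), segment lists, innate-like pairs, non-templated nucleotides and nucleotide variants per protein. Their alternatives were clonotypes of 1 count removed, no downsampling, amino acid clonotypes, each nucleotide clonotype counted once, the Jaccard index for overlap and every library left out in turn. The F2 overlap of 2 libraries is the sum over shared clonotypes (CDR3 nucleotides, TRAV family and TRAJ) of the geometric mean of their frequencies at 5952 counts. Measures were compared by 2-sided exact permutation over all 70 arrangements, and the lineages across states by 100000 resamples within states. Comparisons of POS with NEG across lineages and interactions used the 4900 exact arrangements. Chosen after seeing the data were the same tests without each library, with each clonotype counted once and with nucleotide variants at equal depth, all arrangements listed, and exact tests that flip the signs of POS minus NEG over pairs of the same number, also without each pair.

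The fixed lists were J-proximal TRAV families 17 to 21, 5-prime-most TRAV families 1 and 2, V-proximal (TRAJ40 and above), central (TRAJ21 to TRAJ39) and C-proximal (up to TRAJ20) TRAJ segments, D and N copies of the duplicated TRAV genes, and the pairs of iNKT, MAIT and type II NKT-associated cells. In these cells, sorted as negative for CD1d tetramer, canonical iNKT CDR3s had 0 counts in every library. Canonical MAIT CDR3s had 11 counts in resting Treg, 1 in POS Teff and 0 elsewhere. In each comparison the text names the TRAV genes with a mean share of at least 0.5% in 1 of the groups and the largest changes that passed, up to 4 in each direction, up to 3 TRAJ genes in each direction, and up to 4 clonotypes in each direction found in all 4 libraries of the higher group.

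Whether replicate numbers pair the samples was examined before any model was fitted, from the correlation of deviations from group means within each number. It was 0.44 to 0.64 for segments between NEG and POS Teff and 0.28 to 0.47 between NEG and POS aTreg, with every pair above 0.1, the limit set for pairing. In the other 5 comparisons at least 1 pair was below it. POS Teff and POS aTreg came closest, at 0.0528 to 0.127 for segments and 0.0401 to 0.329 for clonotypes, positive in all 4 pairs, and their F2 overlap was 0.0512 within a number and 0.0240 between numbers. For NEG Teff it was 0.0640 and 0.0360 with POS aTreg, and 0.0602 and 0.0460 with NEG aTreg, so some sharing by number also crosses the lineages. The F2 overlap between libraries of different groups averaged 0.112 within a number and 0.0675 between numbers (permutation p = 6e-05). The blocked value stands beside the comparisons of POS with NEG cells.

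Recovery was tested on simulated data, drawn from each comparison's means, library totals and dispersions, with known segments or clonotypes changed. Of 4-fold (2-fold) changes in segments, 81.8% (33.3%) were found in NEG Teff–Tnaive, 72.7% (8.33%) in POS–NEG Teff and 100% (81.8%) in NEG aTreg–resting Treg. Found were 90.9% (45.5%) in POS–NEG aTreg and 100% (90.9%) in resting Treg–Tnaive. The last 2 were 72.7% (27.3%) in NEG aTreg–NEG Teff and 54.5% (16.7%) in POS aTreg–POS Teff. For a 64-fold change in clonotypes, the recovered share in the same order was 52.2%, 0.114%, 56.1%, 22.5%, 52.3%, 44.8% and 47.8%, and false calls made up 0% to 5.98% of clonotype calls over 20 rounds. For segments, with 1 round each, false calls made up 7.14%, 10.0%, 5%, 0%, 0%, 0% and 11.1% of 14, 10, 20, 15, 21, 11 and 9 calls. Without a block, even 64-fold clonotype changes between POS and NEG Teff were therefore almost never found.

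Left out were out-of-frame clonotypes, since the tables list none, and NEG against POS cells across lineages, which the design does not ask for. Up to 3.41% of a library's counts have a CDR3 that does not end in phenylalanine or tryptophan. They were kept.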

Results

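T cell receptor alpha (TCRα) repertoires were sequenced from splenic CD4 T cells of male C57BL/6 mice aged 3 months. The mice carried a Foxp3-GFP reporter, which marks regulatory T cells (Treg), a DO11.10 TCRβ transgene, which fixes the beta chain, and a single functional Tcra allele. The Foxp3-negative conventional cells (Tconv) were sorted as naive cells (Tnaive), activated CD49b-negative cells (NEG Teff) and activated CD49b-positive cells (POS Teff). The Foxp3-positive cells were sorted as resting Treg, activated CD49b-negative cells (NEG aTreg) and activated CD49b-positive cells (POS aTreg). CD49b is the integrin alpha 2 chain, and activation was read from high CD44. Each of the 6 populations had 4 libraries, 24 in all.

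The libraries held 432157 clone counts in 56349 nucleotide clonotypes, which coded for 36258 amino acid clonotypes (TRAV family plus CDR3, the loop that contacts peptide). The totals of libraries 1 to 4 were 26677, 28589, 24382 and 23630 counts in Tnaive, 27594, 28739, 16023 and 42990 in NEG Teff, and 24455, 19353, 20458 and 20356 in POS Teff. They were 5952, 7619, 7497 and 7169 in resting Treg, 12753, 9936, 12462 and 13616 in NEG aTreg, and 12816, 13016, 13204 and 12871 in POS aTreg. A clonotype with 0 counts in a whole group can still hold up to 0.00290% in Tnaive, 0.00260% in NEG Teff, 0.00355% in POS Teff, 0.0106% in resting Treg, 0.00615% in NEG aTreg and 0.00578% in POS aTreg (3 counts of the group's total). These limits and all intervals cover counting error only. Nothing in the labels says that replicates came from separate animals, so the p-values measure the spread between these samples.

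Values are shares of a library's counts, as mean ± SD with n = 4 libraries per group unless stated. Changes in segments and clonotypes are differences between sorted groups, not followed over time, and carry edgeR adjusted p-values. Measures of whole repertoires were compared with 2-sided exact permutation tests, whose smallest p for 4 against 4 libraries is 0.0286, with Benjamini-Hochberg values over the 7 comparisons beside them. Segment positions are on chromosome 14 of GRCm38, from the GENCODE vM21 annotation. Between 90.9% and 97.9% of a library's counts had at least 2 V hits listed, whose scores were not compared. The copy within a TRAV family is therefore less certain than the family.

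NEG Teff were compared with Tnaive to ask how the repertoire of activated conventional cells differs from that of naive ones. 6 of the 14 tested TRAJ segments from the end of the array nearest the TRAV genes (V-proximal) passed as higher in NEG Teff and the other 8 did not pass, and junctions held more non-templated nucleotides. TRAJ48 (54169808 to 54169868) was 1.65% ± 0.324 in NEG Teff and 0.316% ± 0.0777 in Tnaive (log2 change 2.38 ± 0.29 SE, adjusted p = 8.2e-05), and TRAJ50 (54167590 to 54167652) was 1.04% ± 0.710 against 0.191% ± 0.0262 (2.43 ± 0.50, adjusted p = 0.0023). TRAJ34 (54184699 to 54184756) fell to 2.09% ± 0.635 from 10.4% ± 0.326 (−2.31 ± 0.31, adjusted p = 0.000177). CDR3s held 3.45 ± 0.261 non-templated nucleotides, the bases added at the V–J junction, against 1.68 ± 0.00997 in Tnaive (exact p = 0.0286, Benjamini-Hochberg p = 0.0400).

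Among TRAV genes, TRAV9N-4 (53294341 to 53295030) rose to 1.8% ± 0.248 from 0.188% ± 0.0340 (log2 change 3.25, adjusted p = 8.26e-06), and TRAV13-1 (53545014 to 53545525) to 0.780% ± 0.156 from 0.0830% ± 0.0210 (3.22, adjusted p = 5.03e-05). TRAV9-2 (53590857 to 53591514) was 0.510% ± 0.158 against 0.0695% ± 0.0239 (2.86, adjusted p = 0.000285), and TRAV8-1 (53469756 to 53470232) 1.34% ± 0.814 against 0.300% ± 0.0437 (2.16, adjusted p = 0.00175). TRAV14N-1 (53166626 to 53167178) fell to 0.0423% ± 0.0486 from 0.969% ± 0.0481 (−4.51, adjusted p = 0.000691; −5.70 without NEG Teff 1). TRAV5N-4 (53312904 to 53313422) fell to 0.448% ± 0.240 from 1.23% ± 0.115 (−1.47, adjusted p = 0.00548). TRAV3D-3 (52972448 to 52973038) was 1.56% ± 0.315 against 7.61% ± 0.0700 (−2.28, adjusted p = 5.03e-05) and TRAV6D-7 (53007612 to 53008098) 0.783% ± 0.261 against 2.16% ± 0.392 (−1.46, adjusted p = 0.00188). With each nucleotide clonotype counted once, these last genes gave −0.24 (adjusted p = 0.0513) and −0.01 (adjusted p = 0.991).

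TRAJ16 (54203134 to 54203194) fell to 2.37% ± 0.769 from 6.26% ± 0.682 (−1.40, adjusted p = 0.00274), and TRAJ17 (54201775 to 54201837) to 3.68% ± 1.48 from 9.60% ± 0.696 (−1.38, adjusted p = 0.00583). TRAJ56 (54159263 to 54159325) was 14.8% ± 24.5 against 0.669% ± 0.117 (4.47, adjusted p = 0.00385), a mean set by NEG Teff 4, where it held 51.5% (95% Wilson interval 51.0 to 52.0). Without that library TRAJ56 was 2.58% ± 0.576 (n = 3; log2 change 1.95, adjusted p = 0.0197). In the same library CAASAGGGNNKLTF (TRAV14) held 44.9% of counts (Wilson interval 44.4 to 45.4).

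By fixed list, 6 of the 14 tested V-proximal TRAJ segments rose and 0 fell, 1 of 16 central segments rose and 1 fell, and 2 of 13 C-proximal segments rose and 3 fell. The counts were the same adjusted over the list alone. Among J-proximal TRAV families (TRAV17 to TRAV21), 2 of 3 members rose, and among the 5-prime-most families (TRAV1 and TRAV2), 1 of 2, also when adjusted over the list alone. Of 38 D and N copies, 11 rose and 8 fell (12 and 8 adjusted over the list alone). Without NEG Teff 4 these counts were 8 higher and 1 lower for V-proximal, 6 and 2 for central and 5 and 4 for C-proximal TRAJ, 3 and 0 for J-proximal and 2 and 0 for 5-prime-most TRAV, and 16 and 10 for D and N copies. V-proximal TRAJ segments together held 28.7% ± 20.9 against 8.81% ± 0.780 (exact p = 0.0286, Benjamini-Hochberg p = 0.10; 0.0857 without any 1 Tnaive library), and 18.3% ± 2.13 without NEG Teff 4. Central segments held 40.8% ± 10.7 against 50.5% ± 1.8 and C-proximal segments 30.5% ± 10.2 against 40.7% ± 2.57 (exact p = 0.0286 and Benjamini-Hochberg p = 0.10 for both; up to 0.114 without 1 Tnaive library). For C-proximal segments the difference without NEG Teff 4 was −5.13 points (exact p = 0.0571), and for central segments it was 0.0642 with each clonotype counted once.

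In all, 51 of 118 segments passed (37 higher, 14 lower). TMM scaling moved the median log2 change of all segments by −0.28 and gave 36 higher and 29 lower, and DESeq2 size factors moved it by −0.37 and gave 36 higher and 32 lower. Under TMM the lists read 6 higher and 1 lower for V-proximal, 1 and 5 for central, and 11 and 12 for D and N copies. Without NEG Teff 4, 80 segments passed.

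Clonotypes with a mean share above 1% in NEG Teff included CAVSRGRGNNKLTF (TRAV7) at 1.42% ± 0.260, which had 0 counts in Tnaive and was at least 488-fold higher (adjusted p = 0.00134). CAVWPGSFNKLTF (TRAV7) at 1.09% ± 1.77 was at least 377-fold higher (adjusted p = 0.00428), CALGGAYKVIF (TRAV12) at 0.593% ± 0.269 at least 204-fold (adjusted p = 0.00134) and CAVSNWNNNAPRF (TRAV7) at 0.563% ± 0.689 at least 194-fold (adjusted p = 0.00222). The limit for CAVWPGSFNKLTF was 73.1-fold without NEG Teff 1 (mean 0.212%), and that for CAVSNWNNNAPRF 76.7-fold without NEG Teff 3 (0.223%). In the other direction, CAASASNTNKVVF (TRAV14) held 2.58% ± 0.264 of Tnaive and 0.00493% ± 0.00608 of NEG Teff (4 counts), and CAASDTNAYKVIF (TRAV14) held 2.42% ± 0.231 and 0.00156% (1 count). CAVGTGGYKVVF (TRAV7) and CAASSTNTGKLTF (TRAV14) had 0 counts in NEG Teff and were at least 120-fold and 97.0-fold lower there (adjusted p = 0.00134 for all 4; 75.4-fold and 60.9-fold without NEG Teff 4). Of 1803 amino acid clonotypes tested, 1098 passed (244 higher, 854 lower), and 662 of them were absent from 1 of the groups. The filter admits such a clonotype only if all 4 libraries of the other group hold it. All 662 of these that were tested passed, against 436 of 1141 found in both groups. DESeq2 gave 296 higher and 496 lower and moved the median log2 change by 1.13 (TMM by 0.78). Cut down to equal depth, 488 clonotypes passed (110 higher, 378 lower). Leaving out 1 library gave 481 to 932 with the detection filter applied again (481 to 500 without a Tnaive library) and 1013 to 1152 with the same clonotypes tested. Of the 1098 calls, 1092 also passed a test of counting error alone, and 73 had a p in edgeR below that test's p.

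At an equal depth of 5952 counts, NEG Teff held 2120 ± 514 nucleotide clonotypes and Tnaive 2778 ± 47.5 (exact p = 0.0286, Benjamini-Hochberg p = 0.0667; 0.0857 without any 1 Tnaive library and 0.114 with clonotypes of 1 count removed). Mean CDR3 length was 13.44 ± 0.202 against 12.98 ± 0.0135 amino acids (exact p = 0.0286, Benjamini-Hochberg p = 0.0667). Clonotypes with no non-templated nucleotide held 16.3% ± 4.69 against 38.5% ± 0.626 (exact p = 0.0286, Benjamini-Hochberg p = 0.10). Strongly interacting residues (leucine, phenylalanine, isoleucine, methionine, valine, tryptophan, cysteine and tyrosine) made up 13.3% ± 2.99 of the CDR3 centre against 13.4% ± 0.0640 (exact p = 1.00), and the difference was 1.30 points without NEG Teff 4 and 1.21 points with each clonotype counted once (exact p = 0.0286 for both). The type II NKT-associated pair TRAV9–TRAJ9 held 0.0680% ± 0.0378 against 0.0126% ± 0.00705 (exact p = 0.0286, Benjamini-Hochberg p = 0.0667; 0.0571 without any 1 Tnaive library). The iNKT pair TRAV11–TRAJ18 had 5 counts in NEG Teff and 3 in Tnaive, and the MAIT pair TRAV1–TRAJ33 had 3 and 1, too few to compare at this depth. The sort for cells negative for CD1d tetramer leaves out iNKT cells, so the low iNKT counts cannot be read as an effect of depth or activation.

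**Figure D1:**
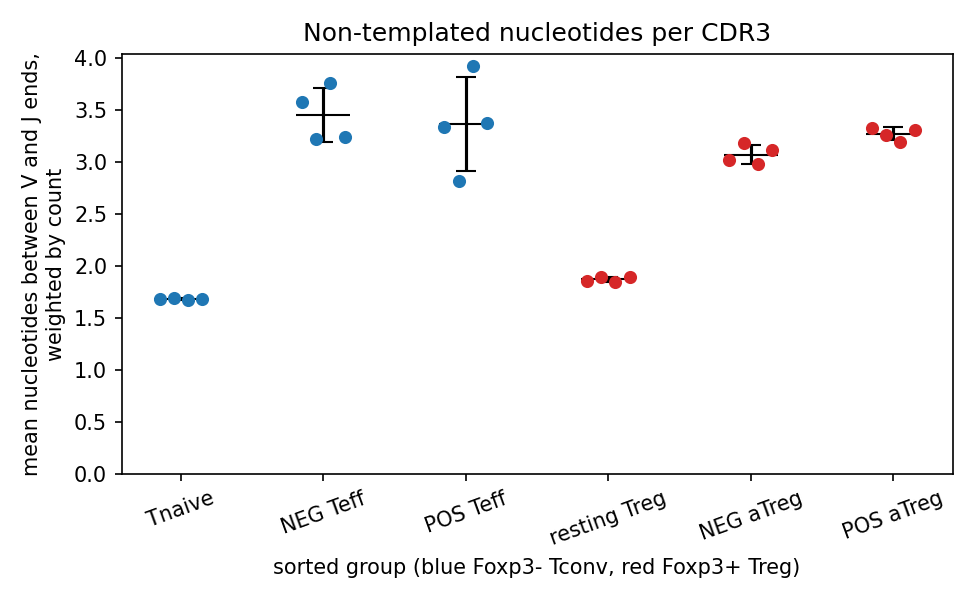
Non-templated nucleotides per CDR3, weighted by counts, in each of the 24 libraries (points), with the mean and SD of each of the 6 groups. Tnaive (1.68 ± 0.00997) and resting Treg (1.87 ± 0.0233) lie below the 4 activated groups, whose means run from 3.07 to 3.45.

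POS Teff were compared with NEG Teff to ask whether CD49b marks a different part of the activated conventional repertoire. No TRAV or TRAJ segment passed in edgeR (0 of 116, with 5 at an unadjusted p under 0.05). TRAV21/DV12 (53875984 to 53876752) was at 0.811% ± 0.393 in POS Teff and 0.210% ± 0.0798 in NEG Teff, and TRAV6D-3 (52725299 to 52726919) was at 0.868% ± 0.281 against 0.326% ± 0.133. These 2 and TRAV7-2 (53390635 to 53391142; 0.624% ± 0.183 against 0.209% ± 0.0278), named after their values were seen, were the 3 segments called by DESeq2 (adjusted p = 0.0164, 0.0264 and 0.0286). TMM called 0.

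No clonotype passed either (0 of 895, with 137 at an unadjusted p under 0.05; TMM 0, DESeq2 47). Libraries of the same number shared clonotypes, and with that number as a block 59 clonotypes passed, 20 higher and 39 lower, while segments stayed at 0. Among those 59, named after their values were seen, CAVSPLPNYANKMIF was 0.246% ± 0.143 in POS Teff and 0.000906% in NEG Teff (1 count), higher in all 4 pairs (adjusted p = 1.01e-07). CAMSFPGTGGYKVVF (TRAV6) was 1.30% ± 0.635 against 0.375% ± 0.258 (log2 change 1.9, adjusted p = 0.00023). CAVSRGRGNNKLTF (TRAV7) was lower in POS Teff, at 0.489% ± 0.241 against 1.42% ± 0.260 (−1.65, adjusted p = 0.00152), as was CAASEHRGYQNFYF at 0.133% ± 0.0512 against 0.589% ± 0.233 (−2.14, adjusted p = 0.00488). The mean F2 overlap, the summed geometric means of shared clonotype frequencies, was 0.486 ± 0.117 between NEG and POS Teff of the same number and 0.121 ± 0.0255 between different numbers. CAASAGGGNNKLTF, the 44.9% clonotype of NEG Teff 4, held 26.2% of POS Teff 4 (Wilson interval 25.6 to 26.8).

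In the fixed lists, none of the 3 J-proximal and 2 5-prime-most TRAV, 14 V-proximal, 16 central and 13 C-proximal TRAJ segments or 35 D and N copies passed over all segments. Adjusted over the list alone, 1 of the 3 J-proximal TRAV members passed as higher, and none of the others. POS Teff held 1545 ± 193 clonotypes at equal depth against 2120 ± 514 (exact p = 0.114; −819 and exact p = 0.0286 without NEG Teff 4). Non-templated nucleotides were 3.37 ± 0.452 against 3.45 ± 0.261 (exact p = 0.771). Strong residues were 15.3% ± 1.8 of the CDR3 centre against 13.3% ± 2.99, a difference smaller than the SD of NEG Teff. They were higher in POS Teff in all 4 pairs of the same number, by 1.98 points on average. The exact paired p was 0.125, the lowest that 4 pairs can give (Benjamini-Hochberg p = 0.611). The TRAV9–TRAJ9 pair held 0.122% ± 0.0756 against 0.0680% ± 0.0378 (exact p = 0.229, and 0.0286 without POS Teff 4). POS Teff had 0 counts of the iNKT pair and 1 of the MAIT pair. The F2 overlap with NEG aTreg was lower for POS Teff than for NEG Teff (0.0271 ± 0.00238 against 0.0496 ± 0.00929, exact p = 0.0286, Benjamini-Hochberg p over 8 overlap tests 0.137; 0.0571 without any 1 POS Teff library). The other 7 overlap tests gave exact p from 0.0571 to 0.257.

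**Figure D2:**
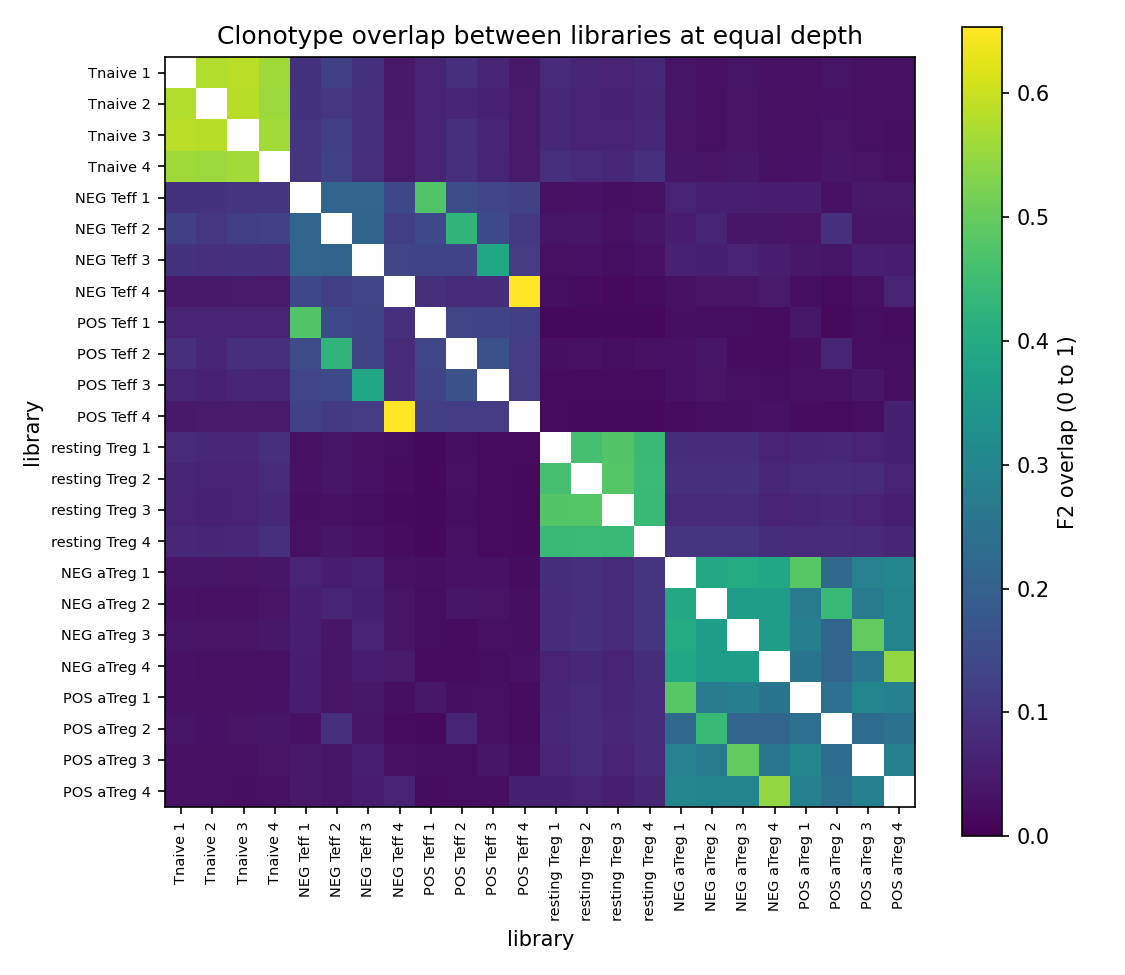
F2 overlap (colour, 0 to 1) between each pair of the 24 libraries at equal depth, ordered by group and replicate on both axes, with each library's overlap with itself left blank. Within groups, Tnaive libraries overlap most (0.571 ± 0.0128) and POS Teff least (0.131 ± 0.0182), and NEG and POS libraries of the same number stand out (0.486 ± 0.117 in Teff, 0.492 ± 0.0438 in aTreg).

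NEG aTreg were compared with resting Treg, the same activation step in the Treg lineage. 5 of 14 V-proximal TRAJ segments passed as higher in NEG aTreg, and 8 of 13 C-proximal ones passed as lower. TRAJ43 (54174742 to 54174798) rose to 5.78% ± 0.661 from 1.58% ± 0.386 (log2 change 1.87 ± 0.19 SE, adjusted p = 1.37e-06), and TRAJ9 (54209393 to 54209450) fell to 1.93% ± 0.525 from 8.17% ± 2.08 (−2.08 ± 0.22, adjusted p = 2.07e-06). Non-templated nucleotides were 3.07 ± 0.0914 against 1.87 ± 0.0233 (exact p = 0.0286, Benjamini-Hochberg p = 0.0400). Repertoires were less diverse, with 1981 ± 177 clonotypes at equal depth against 3044 ± 81.6 (exact p = 0.0286, Benjamini-Hochberg p = 0.0667), which turned to 76.5 more (exact p = 0.314) with clonotypes of 1 count removed.

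TRAV13-1 rose to 1.63% ± 0.539 from 0.117% ± 0.0216 (log2 change 3.79, adjusted p = 7.66e-07), TRAV3-3 (53665929 to 53666506) to 3.73% ± 0.968 from 0.581% ± 0.113 (2.69, adjusted p = 7.66e-07), and TRAV12-2 (53616315 to 53616914) to 3.66% ± 0.904 from 1.01% ± 0.132 (1.86, adjusted p = 5.47e-06). TRAV17 (53806639 to 53807115) was 0.950% ± 0.729 against 0.110% ± 0.0539 (3.08, adjusted p = 0.000205; 2.40 without NEG aTreg 3). TRAV7D-4 (52769753 to 52770392) fell to 0.759% ± 0.256 from 3.47% ± 1.76 (−2.20, adjusted p = 0.000478), TRAV12-3 (53621657 to 53622245) to 0.495% ± 0.182 from 1.95% ± 0.198 (−1.98, adjusted p = 3.93e-05), TRAV12D-2 (52915799 to 52916426) to 0.368% ± 0.129 from 1.10% ± 0.242 (−1.58, adjusted p = 0.000613) and TRAV3-1 (52580665 to 52581213) to 0.402% ± 0.0753 from 1.00% ± 0.197 (−1.31, adjusted p = 0.000665). TRAJ56 rose to 3.01% ± 0.979 from 0.491% ± 0.121 (2.61, adjusted p = 2.12e-06) and TRAJ49 (54168686 to 54168747) to 2.57% ± 0.371 from 0.821% ± 0.182 (1.65, adjusted p = 3.93e-05). TRAJ5 (54213777 to 54213838) fell to 0.177% ± 0.104 from 0.875% ± 0.159 (−2.28, adjusted p = 0.000185). TRAJ38 (54180574 to 54180635) fell to 0.338% ± 0.115 from 0.999% ± 0.0854 (−1.55, adjusted p = 0.000446), and with each nucleotide clonotype counted once the change was −0.51 (adjusted p = 0.0601).

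Of the fixed lists, 5 of 14 V-proximal TRAJ segments rose and 0 fell, 7 of 16 central segments rose and 5 fell, and 1 of 13 C-proximal segments rose and 8 fell. Among D and N copies, 7 of 31 rose and 8 fell, 1 of 3 J-proximal TRAV members rose, and the 1 tested 5-prime-most member did not pass. All of these counts were the same adjusted over the list alone. V-proximal TRAJ segments together held 18.7% ± 2.79 against 9.62% ± 0.629 (exact p = 0.0286, Benjamini-Hochberg p = 0.10). C-proximal segments held 25.7% ± 3.18 against 36.1% ± 3.02 (exact p = 0.0286, Benjamini-Hochberg p = 0.10; 0.0571 without NEG aTreg 4). In all, 58 of 108 segments passed (31 higher, 27 lower).

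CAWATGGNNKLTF (TRAV12) at 1.99% ± 0.891, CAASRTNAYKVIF (TRAV7) at 1.41% ± 1.31, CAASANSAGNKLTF (TRAV14) at 1.40% ± 0.187 and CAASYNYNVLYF (TRAV7) at 1.01% ± 0.554 of NEG aTreg had 0 counts in resting Treg. They were at least 188-, 133-, 132- and 95.1-fold higher (adjusted p = 2.31e-05, 6.65e-05, 2.2e-05 and 3.24e-05). Without NEG aTreg 4 the limit for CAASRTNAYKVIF was 75.2-fold (mean 0.799%). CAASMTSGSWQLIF (TRAV7) at 0.444% ± 0.140, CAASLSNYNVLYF (TRAV7) at 0.390% ± 0.184, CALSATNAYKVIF (TRAV12) at 0.380% ± 0.113 and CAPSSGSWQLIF (TRAV13) at 0.298% ± 0.0533 of resting Treg had 0 counts in NEG aTreg, at least 72.2-, 63.4-, 61.8- and 48.5-fold lower (adjusted p from 3.24e-05 to 3.59e-05). Of 966 clonotypes, 699 passed (249 higher, 450 lower), and 422 of these were absent from 1 of the groups. All 422 tested clonotypes absent from 1 group passed, against 277 of 544 found in both. DESeq2 moved the median log2 change by 0.60 and TMM by 0.37. Leaving out 1 library gave 379 to 508 with the filter applied again (379 to 394 without a resting Treg library) and 652 to 695 with the same clonotypes tested. Of the 699 calls, 691 also passed the test of counting error alone, and 104 had a p below that test's p.

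CDR3s were 13.27 ± 0.0745 against 13.04 ± 0.0190 amino acids long (exact p = 0.0286, Benjamini-Hochberg p = 0.0667). Clonotypes with no non-templated nucleotide held 20.2% ± 1.97 against 38.0% ± 0.556 (exact p = 0.0286, Benjamini-Hochberg p = 0.10). Strong residues were 16.7% ± 0.483 against 17.5% ± 0.620 (exact p = 0.114, and 0.0286 without resting Treg 4). In the 3 central residues alone the direction turned, with 1.57 points more in NEG aTreg (exact p = 0.0286). The TRAV9–TRAJ9 pair held 0.189% ± 0.101 against 0.0431% ± 0.0129 (exact p = 0.0286, Benjamini-Hochberg p = 0.0667; 0.0571 without any 1 resting Treg library). The MAIT pair held 0.0424% ± 0.0258 against 0.0452% ± 0.0232, less than the spread between libraries, while the canonical MAIT CDR3s had 0 counts in NEG aTreg and 11 in resting Treg (0.0377% ± 0.0302, and 0.0240% without resting Treg 2; exact p = 0.0286, Benjamini-Hochberg p = 0.10; 0.0857 without any 1 NEG aTreg library). The iNKT pair had 0 counts in every Treg library, in cells sorted as negative for CD1d tetramer.

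**Figure D3:**
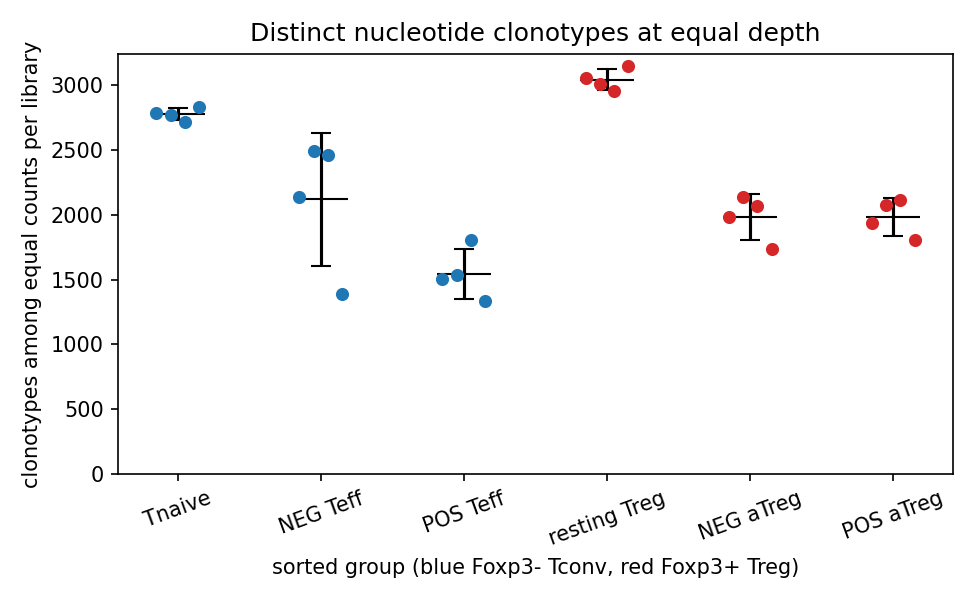
Nucleotide clonotypes among 5952 counts drawn from each of the 24 libraries (points), with the mean and SD of each of the 6 groups. Resting Treg (3044 ± 81.6) lie highest and POS Teff (1545 ± 193) lowest.

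POS aTreg were compared with NEG aTreg to ask whether CD49b marks a different part of the activated Treg repertoire. TRAJ11 (54207139 to 54207197) was the 1 segment of 113 that passed, at 3.55% ± 1.06 in POS aTreg and 1.26% ± 0.383 in NEG aTreg (log2 change 1.5 ± 0.30 SE, adjusted p = 0.0260). A pair of TRAV14 clonotypes was higher in POS aTreg. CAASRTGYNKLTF held 0.757% ± 0.632 (0.470% without POS aTreg 1) against 0.00252% (1 count; adjusted p = 0.000488), and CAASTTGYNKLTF held 0.346% ± 0.241 against 0 counts, at least 56.3-fold (adjusted p = 0.00112; 37.2-fold without POS aTreg 4). Non-templated nucleotides were 3.27 ± 0.0612 against 3.07 ± 0.0914 (exact p = 0.0286, Benjamini-Hochberg p = 0.0400), a difference that gave exact p = 0.0571 without any 1 POS aTreg library or without NEG aTreg 1 or 3.

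The TRAJ11 call did not hold without any 1 of 6 libraries (POS aTreg or NEG aTreg 1, 3 or 4; adjusted p up to 0.147), nor with each nucleotide clonotype counted once (log2 change 0.33, adjusted p = 0.319). At an unadjusted p under 0.05 there were 20 segments, and DESeq2 called 5. TMM moved the median log2 change of segments by −0.15. With the replicate number as a block 3 segments passed, TRAJ11 (1.5), TRAJ56 at 1.66% ± 0.886 against 3.01% ± 0.979 (−0.93) and TRAV7-4 (53461099 to 53461738) at 5.58% ± 1.76 against 9.72% ± 1.93 (−0.84), all at adjusted p = 0.0256. By fixed list, 1 of 13 C-proximal TRAJ segments rose (1 higher and 1 lower adjusted over the list alone). None of the 3 J-proximal or 1 5-prime-most TRAV, 14 V-proximal or 16 central TRAJ segments or 34 D and N copies passed, also when adjusted over the list alone.

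Of 930 clonotypes 6 passed (5 higher, 1 lower; 141 at an unadjusted p under 0.05; DESeq2 52, TMM 8), 4 of them among the 30 tested that were absent from 1 of the groups. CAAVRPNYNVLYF (TRAV4) at 0.176% ± 0.0560 and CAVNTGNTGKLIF (TRAV7) at 0.170% ± 0.162 had 0 counts in NEG aTreg, at least 28.6- and 27.6-fold (adjusted p = 0.0128 and 0.0243; 0.20 and 0.214 with no detection filter). With the same clonotypes tested, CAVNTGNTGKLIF lost its call without any 1 of POS aTreg 2 or 4 or NEG aTreg 1 or 3 (adjusted p up to 0.0825), and its limit was 17.5-fold without POS aTreg 4. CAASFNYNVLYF (TRAV7) was lower, at 0.0230% ± 0.0165 against 0.399% ± 0.176 (log2 change −4.06, adjusted p = 0.0423), and lost its call without any 1 of 6 libraries (adjusted p up to 0.102), with no filter (0.326) and with all 6 groups in 1 fit (0.0786). With the replicate number as a block 79 clonotypes passed, 35 higher and 44 lower. They included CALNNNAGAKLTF at 0.149% ± 0.0611 against 0 counts, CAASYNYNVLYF at 0.138% ± 0.127 against 1.01% ± 0.554 (−3.14, adjusted p = 8.18e-07) and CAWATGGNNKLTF at 0.507% ± 0.407 against 1.99% ± 0.891 (−2.16, adjusted p = 4.46e-05), named after their values were seen. Without any 1 of POS aTreg 1, 2 or 3 the count without a block was 1, and with the same clonotypes tested 3 to 8.

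POS aTreg held 1984 ± 143 clonotypes at equal depth against 1981 ± 177 (exact p = 0.971), and CDR3s of 13.4 ± 0.119 against 13.3 ± 0.0745 amino acids. Strong residues were 16.4% ± 1.99 against 16.7% ± 0.483, less than the spread between libraries. The MAIT pair had 0 counts in POS aTreg and 20 in NEG aTreg (0.0424% ± 0.0258; exact p = 0.0286, Benjamini-Hochberg p = 0.0667; 0.0571 without any 1 POS aTreg library), and the canonical MAIT CDR3s had 0 counts in both. The F2 overlap with resting Treg was 0.0713 for POS aTreg and 0.0843 for NEG aTreg (exact p = 0.0857). NEG and POS aTreg of the same number overlapped at 0.492 ± 0.0438 and of different numbers at 0.263 ± 0.0315. Over the 4 pairs of the same number, 9 of 22 measures moved the same way in every pair, with an exact paired p of 0.125 each, the lowest that 4 pairs can give (Benjamini-Hochberg p = 0.306). Higher in POS aTreg were normalised Shannon entropy (by 0.0213), CDR3 length (0.127 amino acids, 0.0731 without pair 2), non-templated nucleotides (0.201), C-proximal TRAJ segments (3.63 points), 5-prime-most TRAV families (0.708 points, 0.253 without pair 1) and cysteine in the CDR3 centre (0.192 points, 0.127 without pair 1). Lower were the 10 most abundant clonotypes (−3.30 points), V-proximal TRAJ segments (−2.04 points) and the MAIT pair (−0.0424 points).

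Resting Treg were compared with Tnaive to ask how the lineages differ among resting or naive cells. Resting Treg used TRAV6-6 (53516929 to 53517366) at 3.8% ± 0.373 against 0.442% ± 0.0260 (log2 change 3.10 ± 0.11 SE, adjusted p = 5.97e-12) and TRAV3D-3 at 0.950% ± 0.120 against 7.61% ± 0.0700 (−2.99 ± 0.09, adjusted p = 2.65e-12). TRAJ34 was 2.22% ± 0.144 against 10.4% ± 0.326 (−2.22 ± 0.07, adjusted p = 2.79e-12). Strong residues in the CDR3 centre were higher in resting Treg, 17.5% ± 0.620 against 13.4% ± 0.0640 (exact p = 0.0286, Benjamini-Hochberg p = 0.10), as was its net charge, 0.163 ± 0.00436 against 0.0605 ± 0.00427 (exact p = 0.0286, Benjamini-Hochberg p = 0.20). Non-templated nucleotides were 1.87 ± 0.0233 against 1.68 ± 0.00997 (exact p = 0.0286, Benjamini-Hochberg p = 0.0400), a direction that turned to −0.0852 with each clonotype counted once.

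TRAV7D-4 was 3.47% ± 1.76 against 0.433% ± 0.208 (2.98, adjusted p = 2.16e-05), TRAV7-1 (52654817 to 52655328) 1.59% ± 0.0850 against 0.271% ± 0.0495 (2.54, adjusted p = 2.29e-09) and TRAV12D-3 (52929789 to 52930282) 5.79% ± 0.412 against 1.10% ± 0.170 (2.40, adjusted p = 1.48e-10). TRAV14N-1 was lower, at 0.0265% ± 0.0326 against 0.969% ± 0.0481 (−5.06, adjusted p = 2.16e-08; −6.00 without resting Treg 3). So were TRAV6D-7 at 0.583% ± 0.0198 against 2.16% ± 0.392 (−1.88, adjusted p = 5.01e-08) and TRAV5-4 (53704007 to 53704514) at 0.982% ± 0.259 against 3.47% ± 0.283 (−1.81, adjusted p = 5.3e-08). TRAJ5 (0.875% ± 0.159 against 0.170% ± 0.0287; 2.37, adjusted p = 6.07e-08), TRAJ6 (54212688 to 54212749; 1.52% ± 0.284 against 0.327% ± 0.0571; 2.22, adjusted p = 5.01e-08) and TRAJ38 (0.999% ± 0.0854 against 0.282% ± 0.0282; 1.81, adjusted p = 5.92e-08) were higher. TRAJ17 (2.88% ± 0.439 against 9.60% ± 0.696; −1.74, adjusted p = 1.95e-09) and TRAJ16 (2.02% ± 0.0651 against 6.26% ± 0.682; −1.63, adjusted p = 1.86e-09) were lower.

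In all, 83 of 113 segments passed (52 higher, 31 lower). TMM moved the median log2 change by −0.36 and gave 37 higher and 41 lower, and DESeq2 moved it by −0.35 and gave 36 higher and 40 lower. By list, 4 of 14 V-proximal TRAJ segments were higher and 1 lower (TMM 3 and 5), 8 of 16 central higher and 4 lower (TMM 3 and 5), and 8 of 13 C-proximal higher and 4 lower (TMM 7 and 5). Of 35 D and N copies 18 were higher and 11 lower (TMM 13 and 14), the 1 tested 5-prime-most TRAV member was higher, and none of the 3 J-proximal members passed. These counts were the same adjusted over the list alone. The V-proximal sum was 9.62% ± 0.629 against 8.81% ± 0.780, and its difference turned to −2.47 points with each clonotype counted once.

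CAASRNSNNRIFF (TRAV7) held 1.99% ± 0.345 of resting Treg and 0.00187% of Tnaive (2 counts; adjusted p = 7.14e-13). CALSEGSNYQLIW (TRAV12) at 0.656% ± 0.0503, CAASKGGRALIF (TRAV10) at 0.504% ± 0.0737 and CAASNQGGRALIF (TRAV7) at 0.470% ± 0.194 had 0 counts in Tnaive, at least 226-, 173- and 162-fold higher (adjusted p = 5.06e-12, 1.71e-11 and 1.74e-10). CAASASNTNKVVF, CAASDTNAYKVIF, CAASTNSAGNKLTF (TRAV7) and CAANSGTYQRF (TRAV14) held 2.58% ± 0.264, 2.42% ± 0.231, 1.73% ± 0.336 and 1.60% ± 0.398 of Tnaive and had 0 counts in resting Treg, at least 243-, 227-, 163- and 150.5-fold lower. Of 1826 clonotypes, 1323 passed (511 higher, 812 lower), 978 of them absent from 1 of the groups. Of the tested clonotypes absent from 1 group 978 of 1081 passed, against 345 of 745 found in both. Of all 1323 calls, 1189 also passed the test of counting error alone (511 higher, 678 lower), 134 had a counting-error p of at least 0.05, and 343 had a p in edgeR below that test's p. At equal depth 820 passed (400 higher, 420 lower). TMM moved the median log2 change by −0.57 and DESeq2 by −0.51. Leaving out any 1 library gave 612 to 809 with the filter applied again and 1097 to 1328 with the same clonotypes tested.

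Resting Treg held 3044 ± 81.6 clonotypes at equal depth against 2778 ± 47.5 (exact p = 0.0286, Benjamini-Hochberg p = 0.0667), a difference of 266 that turned to −566 with clonotypes of 1 count removed. CDR3s were 13.04 ± 0.0190 against 12.98 ± 0.0135 amino acids long (exact p = 0.0286, Benjamini-Hochberg p = 0.0667; 0.171 with clonotypes of 1 count removed). The MAIT pair had 13 counts in resting Treg (0.0452% ± 0.0232) and 1 in Tnaive (exact p = 0.0286, Benjamini-Hochberg p = 0.0667), and the canonical MAIT CDR3s had 11 (0.0377% ± 0.0302, and 0.0240% without resting Treg 2) and 0 (exact p = 0.0286, Benjamini-Hochberg p = 0.10; 0.0857 without any 1 Tnaive library). The TRAV9–TRAJ9 pair held 0.0431% ± 0.0129 against 0.0126% ± 0.00705 (exact p = 0.0286, Benjamini-Hochberg p = 0.0667; 0.0571 without any 1 Tnaive library).

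NEG aTreg were compared with NEG Teff to ask how the lineages differ after activation. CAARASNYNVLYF (TRAV7) held 6.87% ± 1.66 of NEG aTreg and 0.00178% ± 0.00205 of NEG Teff (2 counts; adjusted p = 0.000228). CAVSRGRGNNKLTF (TRAV7) held 1.42% ± 0.260 of NEG Teff and had 0 counts in NEG aTreg, at least 230.3-fold lower (adjusted p = 0.000228). TRAV6-4 (53454296 to 53454784) was higher in NEG aTreg at 1.03% ± 0.189 against 0.159% ± 0.0275 (log2 change 2.70 ± 0.40 SE, adjusted p = 0.000377), and TRAV4-2 (53418349 to 53418873) was lower at 0.389% ± 0.160 against 2.56% ± 0.366 (−2.72 ± 0.38, adjusted p = 0.000332). Strong residues were 16.7% ± 0.483 of the CDR3 centre against 13.3% ± 2.99 (exact p = 0.0286, Benjamini-Hochberg p = 0.10; 0.0857 without any 1 NEG aTreg library and 0.0571 with each clonotype counted once).

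TRAV5-1 (52622566 to 52623082) was 0.143% ± 0.0217 against 0.726% ± 0.227 (−2.35, adjusted p = 0.00272), TRAV8-1 0.270% ± 0.0975 against 1.34% ± 0.814 (−2.31, adjusted p = 0.00632) and TRAJ16 0.711% ± 0.333 against 2.37% ± 0.769 (−1.74, adjusted p = 0.0112). TRAV13D-2 (52942764 to 52943289; 0.524% ± 0.135 against 1.55% ± 0.694; −1.56, adjusted p = 0.0125), TRAJ48 (0.456% ± 0.335 against 1.65% ± 0.324; −1.86, adjusted p = 0.0112), TRAJ52 (54165316 to 54165381; 0.219% ± 0.0539 against 0.734% ± 0.316; −1.73, adjusted p = 0.0158) and TRAJ33 (54185358 to 54185414; 5.24% ± 0.624 against 2.12% ± 0.663; 1.30, adjusted p = 0.0133) lost their calls without some single library, with adjusted p up to 0.0657. Without NEG aTreg 2 the TRAJ48 change was −2.49. TRAV16N (53351028 to 53351621; 0.697% ± 0.438 against 0.218% ± 0.0780; 1.66, adjusted p = 0.0327), TRAV7-4 (9.72% ± 1.93 against 3.94% ± 1.60; 1.31, adjusted p = 0.0338), TRAV13-1 (1.63% ± 0.539 against 0.780% ± 0.156; 1.07, adjusted p = 0.0492), TRAJ26 (54194490 to 54194549; 8.21% ± 1.54 against 3.82% ± 1.01; 1.10, adjusted p = 0.0431) and TRAJ43 (5.78% ± 0.661 against 2.59% ± 1.40; 1.16, adjusted p = 0.0492) lost theirs without any of 5 or 6 libraries, with adjusted p up to 0.168. With each clonotype counted once, TRAV16N changed by −0.01 (adjusted p = 0.974), TRAV7-4 by 0.11 (0.516) and TRAV13-1 by 0.36 (0.197). Calls also ended for TRAV16N under TMM (0.0921) and with all 6 groups in 1 fit (0.0503), TRAV7-4 with merged D and N copies (0.0714), TRAV13-1 under 5 other settings (adjusted p from 0.0515 to 0.156), TRAJ43 with no filter (0.0665) and TRAJ26 with a block (0.0560).

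In all, 20 of 113 segments passed (9 higher, 11 lower; DESeq2 29, and 8 without NEG aTreg 3). By list, 2 of 14 V-proximal TRAJ segments were higher and 2 lower, 2 of 16 central were higher (1 adjusted over the list alone) and 0 of 13 C-proximal were higher and 3 lower. Of 34 D and N copies 2 were higher and 3 lower, and none of the 3 J-proximal and 1 5-prime-most TRAV members passed, with the same counts adjusted over the list alone. Central TRAJ segments together held 55.6% ± 1.23 against 40.8% ± 10.7, and 46.2% ± 0.930 of NEG Teff without library 4 (exact p = 0.0286, Benjamini-Hochberg p = 0.10; 0.0571 without NEG aTreg 1).

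Other clonotypes higher in NEG aTreg were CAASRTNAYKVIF (1.41% ± 1.31), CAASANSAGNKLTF (1.40% ± 0.187) and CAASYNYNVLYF (1.01% ± 0.554), each with 0 counts in NEG Teff and at least 542-, 537- and 389-fold higher (adjusted p = 0.000271, 0.000228 and 0.000228). These limits were 340.2-, 337- and 244-fold without NEG Teff 4, and 307-fold for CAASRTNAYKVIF without NEG aTreg 4 (mean 0.799%). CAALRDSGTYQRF (TRAV4; 0.434% ± 0.367), CAVSRRSSNNRLTL (TRAV7; 0.398% ± 0.187) and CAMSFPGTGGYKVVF (TRAV6; 0.375% ± 0.258) of NEG Teff had 0 counts in NEG aTreg, at least 70.5-, 64.7- and 61.0-fold lower (adjusted p up to 0.000459; 41.2-fold for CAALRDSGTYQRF without NEG Teff 1 and 40.7-fold for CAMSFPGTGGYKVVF without NEG Teff 2). Of 846 clonotypes, 550 passed (294 higher, 256 lower), 396 of them absent from 1 of the groups. Of the tested clonotypes absent from 1 group 396 of 399 passed, against 154 of 447 found in both. TMM moved the median log2 change by −0.65 and gave 264 higher and 301 lower, and DESeq2 moved it by −1.22 and gave 240 higher and 302 lower. At equal depth 346 passed (210 higher, 136 lower). Leaving out any 1 library gave 294 to 347 with the filter applied again and 523 to 560 with the same clonotypes tested, and with no filter 125 passed. Of the 550 calls, 523 also passed the test of counting error alone, 15 had a counting-error p of at least 0.05, and 45 had a p below that test's p.

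NEG aTreg held 1981 ± 177 clonotypes at equal depth against 2120 ± 514 (exact p = 0.571, and −382 with exact p = 0.0286 without NEG Teff 4). Non-templated nucleotides were 3.07 ± 0.0914 against 3.45 ± 0.261 (exact p = 0.0286, Benjamini-Hochberg p = 0.0400; up to 0.114 without 1 NEG aTreg library). CDR3s were 13.3 ± 0.0745 against 13.4 ± 0.202 amino acids long. The MAIT pair had 20 counts in NEG aTreg (0.0424% ± 0.0258) and 3 in NEG Teff (exact p = 0.0286, Benjamini-Hochberg p = 0.0667; 0.0571 without any 1 NEG Teff library), but the canonical MAIT CDR3s had 0 counts in both groups (exact p = 1.00).

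POS aTreg were compared with POS Teff, the lineage difference among CD49b-positive cells. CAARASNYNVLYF (TRAV7) held 3.20% ± 1.58 of POS aTreg and had 0 counts in POS Teff, at least 902-fold higher (adjusted p = 0.000661), and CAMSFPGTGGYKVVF (TRAV6) held 1.30% ± 0.635 of POS Teff and 0.00189% of POS aTreg (1 count; adjusted p = 0.000661). TRAV6D-3 was 0.0443% ± 0.0116 in POS aTreg and 0.868% ± 0.281 in POS Teff (log2 change −4.27 ± 0.57 SE, adjusted p = 0.000526). TRAV21/DV12 (0.10% ± 0.0597 against 0.811% ± 0.393; −3.01, adjusted p = 0.0155) and TRAV4-2 (0.406% ± 0.145 against 1.82% ± 0.696; −2.16, adjusted p = 0.0155) were also lower, and each lost its call without any 1 of 4 libraries (adjusted p up to 0.0593), TRAV4-2 also with a block (0.0506).

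These were the 3 of 118 segments that passed (30 at an unadjusted p under 0.05; DESeq2 9). The count was 5 without POS Teff 3 and 1 without POS Teff 4, POS aTreg 1 or POS aTreg 2. By list, 1 of 3 J-proximal TRAV members was lower, also when adjusted over the list alone, and 0 of 37 D and N copies were higher and 1 lower (1 and 1 adjusted over the list alone). None of the 2 5-prime-most TRAV or 14 V-proximal, 16 central and 13 C-proximal TRAJ members passed either way.

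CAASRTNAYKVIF (0.976% ± 1.05), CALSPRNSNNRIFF (TRAV12; 0.962% ± 0.234) and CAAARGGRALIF (TRAV14; 0.934% ± 0.332) of POS aTreg had 0 counts in POS Teff, at least 275-, 271- and 263-fold higher (adjusted p = 0.000661 for each; 136-fold for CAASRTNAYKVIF without POS aTreg 4, mean 0.483%). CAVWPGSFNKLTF (1.16% ± 2.03), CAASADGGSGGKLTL (TRAV14; 0.546% ± 0.788) and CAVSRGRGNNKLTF (0.489% ± 0.241) of POS Teff had 0 counts in POS aTreg, at least 201-, 94.5- and 84.6-fold lower (adjusted p up to 0.00154). Without POS Teff 1 the limits for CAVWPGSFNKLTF and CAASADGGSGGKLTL were 25.7- and 28.3-fold (means 0.149% and 0.164%). With no filter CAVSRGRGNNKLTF gave adjusted p = 0.0603. Of 548 clonotypes, 406 passed (280 higher, 126 lower), 306 of them absent from 1 of the groups, and 254 passed at equal depth. Of the tested clonotypes absent from 1 group 306 of 307 passed, against 100 of 241 found in both. TMM moved the median log2 change by −0.23. Without any 1 POS aTreg library the count was 130 to 135 with the filter applied again, and 391 to 411 with the same clonotypes tested, while no filter gave 22. Of the 406 calls, 404 also passed the test of counting error alone, and 20 had a p below that test's p.

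POS aTreg held 1984 ± 143 clonotypes at equal depth against 1545 ± 193 (exact p = 0.0571; 525 more and exact p = 0.0286 without POS Teff 3). Non-templated nucleotides were 3.27 ± 0.0612 against 3.37 ± 0.452 (exact p = 0.600, and 0.0286 without POS Teff 2). Central TRAJ segments held 54.0% ± 2.30 against 44.9% ± 6.82 (exact p = 0.0571, and 0.0286 without POS Teff 2). Strong residues and CDR3 length (16.4% ± 1.99 against 15.3% ± 1.8, and 13.4 ± 0.119 against 13.4 ± 0.0818 amino acids) differed by less than the spread between libraries. The MAIT pair had 0 counts in POS aTreg and 1 in POS Teff.

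Across the 3 states together, Treg exceeded Tconv in strong residues of the CDR3 centre by 2.88 points (permutation p = 0.00065, Benjamini-Hochberg p over 22 measures 0.00286), in net charge by 0.0654 (permutation p = 0.00038, Benjamini-Hochberg p = 0.00286), in central TRAJ segments by 9.23 points (permutation p = 4e-05, Benjamini-Hochberg p = 0.00088) and in the MAIT pair by 0.0279 points (permutation p = 0.00065, Benjamini-Hochberg p = 0.00286). These 4 measures kept a Benjamini-Hochberg p of their permutation tests below 0.05 without each of the 24 libraries in turn, and with each clonotype counted once, at 1.12 points, 0.0431, 2.18 points and 0.0234 points (highest Benjamini-Hochberg p = 0.0389). These tests treat the 24 libraries as independent, although NEG and POS libraries of the same number and lineage shared clonotypes. Only single libraries were left out, never both of a pair, so these p-values may be too low. The means of strong residues, net charge and central TRAJ segments were higher in Treg in each state, but not all of these differences passed. Net charge differed by 0.102 in resting (exact p = 0.0286), 0.0316 in NEG (exact p = 0.229) and 0.0624 in POS cells (exact p = 0.143). Strong residues gave exact p = 0.429 in POS cells, and central segments exact p = 0.0571 in resting and in POS cells. The MAIT pair was 0.0442 points higher in resting and 0.0407 points higher in NEG cells, and −0.00123 points different in POS cells, where POS aTreg had 0 counts and POS Teff 1. The canonical MAIT CDR3s did not pass, at 0.0122 points (permutation p = 0.0292, Benjamini-Hochberg p = 0.0803; 0.00759 points without resting Treg 2), with 11 counts in resting Treg, 1 in POS Teff and 0 in the other groups, so the excess of the pair in NEG aTreg is not one of canonical MAIT CDR3s. The 5-prime-most TRAV families were 0.383 points higher (permutation p = 0.0122, Benjamini-Hochberg p = 0.0447), and 0.208 points higher without POS aTreg 1, where they held 2.81% (permutation p = 0.0323, Benjamini-Hochberg p = 0.0954). The TRAV9–TRAJ9 pair was 0.0633 points higher (permutation p = 0.0156, Benjamini-Hochberg p = 0.0492), and 0.0269 points with each clonotype counted once (permutation p = 0.172). The adjusted p of these last measures was 0.05 or more without 16 and 18 of the 24 libraries, up to 0.164 and 0.0954. Nucleotide variants per amino acid clonotype, at an equal depth of 5952 counts, were lower by −0.0248 (permutation p = 0.0180, Benjamini-Hochberg p = 0.0565). Across both lineages no measure passed adjustment between POS and NEG cells in an unpaired test, whose lowest permutation p was 0.0143 for the MAIT pair at −0.0215 points (Benjamini-Hochberg p = 0.314). Over the 8 pairs of the same number, no measure passed adjustment of exact paired tests either (lowest Benjamini-Hochberg p = 0.172). C-proximal TRAJ segments were higher in POS in 7 of 8 pairs (3.41 points, exact paired p = 0.0156), as were CDR3s with cysteine in their centre (0.144 points, exact paired p = 0.0156), and V-proximal segments were lower in 7 of 8 (−4.65 points, exact paired p = 0.0234). Without Teff pair 4 the V-proximal difference was −2.63 points (exact paired p = 0.0469). NEG Teff without library 4 held 18.3% ± 2.13. The POS Teff mean of 21.5% includes library 4, where TRAJ56 alone held 31.8%, so these means do not come from like libraries. Within 1 lineage 4 pairs give no exact paired p below 0.125. In Teff, 2 measures moved the same way in all 4 pairs, clonotypes at equal depth (−575 in POS) and strong residues (1.98 points), and in aTreg the 9 measures given for that comparison did.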

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

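Of 234 groups of 4 libraries examined, 24 had a library set apart from the other three by more than Dixon's 95% limit on the gap allows, and chance sets apart about 1 in 20. The rules and the tests of differences between lineages were fixed before the data were examined, and the test of sequencing errors was chosen before its result was seen. The tests of these differences without single libraries, with each clonotype counted once and at equal depth were chosen after the results were seen.

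NEG Teff 4 stood apart in entropy (0.713, others 0.899 to 0.929), the share of its 10 most abundant clonotypes (43.1%, others 7.40% to 13.04%), its top clonotype (22.2%, others 1.48% to 1.89%) and TRAJ56 (51.5%, others 2.13% to 3.23%). It also stood apart in V-proximal TRAJ segments (59.9%, others 17.1% to 20.8%), central segments (24.8%, others 45.2% to 47.0%), C-proximal segments (15.3%, others 34.1% to 36.6%) and D and N copies (24.95%, others 49.8% to 49.98%). The top clonotype of POS Teff 4 held 11.2% (others 1.99% to 2.56%), and TRAJ56 held 4.47% of NEG aTreg 4 (others 2.38% to 2.67%). Tnaive 4 differed in central TRAJ segments (53.2%, others 49.5% to 49.7%), C-proximal segments (36.8%, others 41.6% to 42.3%), CDR3 hydropathy (−1.28, others −1.24), TRAV9-2 (0.0339%, others 0.0779% to 0.0839%) and TRAJ6 (0.241%, others 0.352% to 0.357%). Central TRAJ segments held 50.6% of POS aTreg 1 (others 54.8% to 55.6%), and the 10 most abundant clonotypes held 9.10% of resting Treg 4 (others 11.1% to 11.4%). TRAJ48 held 1.17% of NEG Teff 3 (others 1.75% to 1.85%) and TRAV3-1 held 1.29% of resting Treg 1 (others 0.879% to 0.934%). Innate-like pairs were found in a single library of their group at 1 to 5 counts. These were the iNKT pair in NEG Teff 1 (0.0181%, 95% Wilson interval 0.00774 to 0.0424) and the MAIT pair in Tnaive 3 (0.00410%, interval 0.000724 to 0.0232), NEG Teff 4 (0.00698%, interval 0.00237 to 0.0205) and POS Teff 4 (0.00491%, interval 0.000867 to 0.0278, with a canonical CDR3).

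The protein sequence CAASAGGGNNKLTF held 44.9% of NEG Teff 4 in 24 nucleotide versions, 8 of them at 1% or more. Sequencing or PCR errors of the top version would also give neighbours coding another protein, but these held 417 counts against 9747 in the other versions, or 4.28%, which argues against errors as the source. POS Teff 4 held 20 versions at 26.2%, 19 of them shared, while the highest share in a library of another number was 0.0201%. It had 0 counts in Tnaive 4 and resting Treg 4, 7 in NEG aTreg 4 (0.0514%, Wilson interval 0.0249 to 0.106) and 9 in POS aTreg 4 (0.0699%, Wilson interval 0.0368 to 0.133). The design names no biological difference for replicate 4, so no biological explanation was tested, and selection of many precursors with the same protein may be followed up.

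The change from naive or resting to NEG cells differed between lineages, by a test of the difference itself, in 38 of 118 segments (12 more positive in Treg, 26 more negative; 48 at an unadjusted p under 0.05). TMM moved the median segment change by −0.28 in Tconv and 0.046 in Treg, so the 12 and 26 may depend on scale. TRAV3D-3 fell in Tconv (log2 change −2.28) and was 0.82 in Treg (difference 3.10, adjusted p = 5.1e-05), and TRAJ17 was −1.38 and 0.94 (difference 2.32, adjusted p = 0.000445). With each clonotype counted once the Tconv change of TRAV3D-3 was −0.24 (edgeR adjusted p = 0.0513), and no lineage difference is given that way. TRAJ5 was 0.99 in Tconv and −2.30 in Treg (difference −3.28, adjusted p = 0.0069), and TRAV5-1 was 1.42 and −1.32 (difference −2.74, adjusted p = 0.00101). For clonotypes the number was 6 of 391 (5 more positive in Treg, 86 at an unadjusted p under 0.05), among them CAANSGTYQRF (TRAV14). For POS against NEG it was 0 of 122 segments (13 unadjusted) and 0 of 426 clonotypes (39 unadjusted) in edgeR, with no other tool run. Without NEG Teff 4, 45 segments differed, 35 of them among the 38, and 3 clonotypes. Leaving out each other library gave 23 to 32 segments and 3 to 8 clonotypes. The 4 named segments and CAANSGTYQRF kept their calls without each library.

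Among whole-repertoire measures the same difference between lineages reached an unadjusted exact p under 0.05, and none passed adjustment, for central TRAJ segments (11.1 points, exact p = 0.00735, adjusted 0.111), net charge (−0.0706, exact p = 0.0122, adjusted 0.111), the 5-prime-most TRAV families (−0.369 points, exact p = 0.0151, adjusted 0.111), nucleotide variants per protein (0.0796, exact p = 0.0269, adjusted 0.126) and canonical MAIT CDR3s (−0.0377 points, exact p = 0.0286, adjusted 0.126). For POS against NEG it did so for the MAIT pair (−0.0419 points, exact p = 0.0224, adjusted 0.494). Without NEG Teff 4 the difference was 5.71 points for central TRAJ segments (exact p = 0.0143, adjusted 0.0703) and −0.0901 for net charge (exact p = 0.00122, adjusted 0.0269), and without resting Treg 4 it was 12.1 points for central segments (adjusted 0.0269). Canonical MAIT CDR3s gave −0.0240 points without resting Treg 2. With each clonotype counted once, central segments and net charge turned to −1.295 points and 0.00705 (exact p = 0.241 and 0.639). Nucleotide variants per protein rest on all counts, which differ in depth between groups, and at equal depth gave 0.0563 (exact p = 0.0486, adjusted 0.214).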

How the results depend on the processing

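Chosen after seeing the data were the equal-depth clonotype fits, the fits without a library on the same clonotypes, the limits without a library, the newer quasi-likelihood method, the test of counting error alone, the fits without both libraries numbered 4, entropy and top-10 share without downsampling, each clonotype counted once for measures other than CDR3 length and strong residues, and all alternatives to the tests over combined states or pairs and between lineages. Out-of-frame clonotypes were to be included as an alternative, which was not run because the tables list none. The number of calls, whatever their direction, stayed close to the main one in 40 of 50 segment and 52 of 64 clonotype alternatives. The side of the threshold was kept in 20 of 28 richness, 13 of 14 CDR3 length, 17 of 21 strong-residue, 21 of 24 overlap and 101 of 119 other-measure alternatives, and for named features in 600 of 623. A turn of direction counted against these only where 1 of the values passed the threshold. The 623 hold no fit with merged copies for named D and N copies or TRAV21/DV12, or on the CDR3 alone for named clonotypes. Of the 688 fits that left a library out for named features, 632 kept the call. For 38 named clonotypes absent from 1 group these fits leave out libraries of that group alone, since the detection filter removes the clonotype without a library of the other group. With the same clonotypes tested, 350 of 360 fits of the 45 named clonotypes, without every library in turn, kept the call.

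With no low-count filter, clonotype counts were 649 (NEG Teff–Tnaive), 445 (NEG aTreg–resting Treg), 125 (NEG aTreg–NEG Teff) and 22 (POS aTreg–POS Teff). Without that filter more clonotypes are adjusted for. At equal depth they were 488 (NEG Teff–Tnaive), 820 (resting Treg–Tnaive), 346 (NEG aTreg–NEG Teff) and 254 (POS aTreg–POS Teff). DESeq2 gave 3 segments and 47 clonotypes for POS–NEG Teff, 5 and 52 for POS–NEG aTreg, and 9 segments for POS aTreg–POS Teff. All 6 groups in 1 fit gave 2 segments for POS–NEG Teff, 47 for resting Treg–Tnaive and 32 for POS aTreg–POS Teff. With replicate number as a block, POS–NEG Teff gave 59 clonotypes, and POS–NEG aTreg 3 segments and 79 clonotypes. Without both libraries numbered 4, POS–NEG Teff gave 0 segments and 0 clonotypes in edgeR. Each clonotype counted once gave 0 segments for POS–NEG aTreg, 37 for NEG aTreg–NEG Teff and 13 for POS aTreg–POS Teff.

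With clonotypes of 1 count removed, richness differences were −265.85 (NEG Teff–Tnaive, exact p = 0.114), 76.5 (NEG aTreg–resting Treg, reversed) and −566 (resting Treg–Tnaive, reversed). With no downsampling they were −1764 (POS–NEG Teff), −3314 (resting Treg–Tnaive, reversed) and −1621 (NEG aTreg–NEG Teff), where depth differs between groups. For POS aTreg–POS Teff the difference was 290 (289.9) at the lower depth and 368 with amino acid clonotypes. CDR3 length for resting Treg–Tnaive was 0.0213 with clonotypes of 1 count removed. Strong residues for NEG Teff–Tnaive were 1.21 counted once, and 1.30 without NEG Teff 4 (both reversed). For NEG aTreg–resting Treg they were −1.61 with clonotypes of 1 count removed and 1.57 over 3 residues (reversed), and for NEG aTreg–NEG Teff 0.806 counted once. The Jaccard index gave −0.00357 (aTreg with NEG Teff), −0.00335 (Teff with resting Treg) and −0.00326 (Teff with POS aTreg), past the threshold. Counted once, these turned: J-proximal TRAV in NEG aTreg–NEG Teff (−0.928), 5-prime-most TRAV in POS–NEG Teff (−0.201), V-proximal TRAJ (−2.47), non-templated nucleotides (−0.0852) and clonotypes without them (1.26) in resting Treg–Tnaive, central TRAJ in NEG Teff–Tnaive (0.0642) and TRAV16N in NEG aTreg–NEG Teff (−0.0108). Apart from the filter and depth, the cause was not tested.

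Leaving out each library, in the order of the report's comparisons (NEG Teff–Tnaive, POS–NEG Teff, NEG aTreg–resting Treg, POS–NEG aTreg, resting Treg–Tnaive, NEG aTreg–NEG Teff, POS aTreg–POS Teff), segments ranged 49 to 80, 0 to 0, 47 to 61, 0 to 1, 82 to 85, 8 to 29 and 1 to 5. Clonotypes ranged 481 to 932, 0 to 2, 379 to 508, 1 to 9, 612 to 809, 294 to 347 and 130 to 323, or, with the same clonotypes tested, 1013 to 1152, 0 to 0, 652 to 695, 3 to 8, 1097 to 1328, 523 to 560 and 391 to 411, so most of the loss came from the filter. Richness ranged −782 to −414, −819 to −451, −1114 to −979.8, −80.7 to 62.7, 231 to 295, −382 to −13.9 and 369.9 to 525. CDR3 length ranged 0.370 to 0.521, −0.114 to 0.0374, 0.202 to 0.262, 0.0699 to 0.158, 0.0470 to 0.0619, −0.233 to −0.0816 and −0.0492 to 0.0366. Strong residues ranged −0.912 to 1.30, 0.543 to 2.85, −1.13 to −0.653, −0.902 to 0.615, 3.90 to 4.37, 1.94 to 4.16 and 0.284 to 2.01. Overlap of POS against NEG aTreg ranged −0.0171 to −0.00962 (resting Treg), −0.00468 to −0.00203 (Tnaive), −0.00908 to −0.00413 (NEG Teff) and 0.00280 to 0.00514 (POS Teff), and of POS against NEG Teff −0.0369 to −0.0125 (Tnaive), −0.0125 to −0.00742 (resting Treg), −0.0268 to −0.0202 (NEG aTreg) and −0.0152 to −0.0100 (POS aTreg).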

Other observations

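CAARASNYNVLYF (TRAV7) was found in all 8 activated Treg libraries. It held 7.11%, 4.46%, 8.10% and 7.81% of NEG aTreg 1 to 4 and 2.41%, 1.37%, 4.76% and 4.26% of POS aTreg 1 to 4. It had 4 counts in resting Treg 2, 3 in resting Treg 4 and 0 in resting Treg 1 and 3, 0 in every Tnaive and POS Teff library, and 1 count in each of NEG Teff 1 and 2. Libraries within a group overlapped most in Tnaive (F2 overlap 0.571 ± 0.0128) and resting Treg (0.459 ± 0.0177), then in NEG aTreg (0.380 ± 0.0174), POS aTreg (0.265 ± 0.0296), NEG Teff (0.173 ± 0.0440) and POS Teff (0.131 ± 0.0182). Across lineages, Tnaive and resting Treg overlapped at 0.0721, NEG Teff and NEG aTreg at 0.0496, and POS Teff and POS aTreg at 0.0308.

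The counts of other splits, the test of expanded clonotypes, both tests of reads in the wrong library and the separate tests of spilled reads and spilled cells were chosen after their results were seen, and the other tests before.

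Activated libraries held more non-templated nucleotides than naive or resting ones, by 1.77 in Tconv and 1.20 in Treg. A few expanded clonotypes taking most counts would leave no difference with each clonotype counted once, but it was 1.12 in Tconv and 0.910 in Treg, at least 13.04 SD, which argues against that as the whole cause. Use of different segments would leave none within pairs of TRAV family and TRAJ, but 84.8% was left in Tconv and 87.7% in Treg. A hypothesis is that activated cells may come more often from clonotypes made with more junctional additions, and the thymic origin or age of the cells was not tested.

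NEG and POS libraries of the same number and lineage shared clonotypes. Reads given to the wrong library among all 24 would appear in other numbers as often. Teff clonotypes at 1% or more (55) had a median of 154 counts in the paired library and 0 in other numbers, which argues against it. In aTreg these were 97 and 0, but only 1 of 29 clonotypes was absent from all other numbers (median 7 of 18 libraries). These medians alone do not show sharing by number there. Reads spilling between paired libraries at a constant rate would make the ratio of shares vary by counting error alone, but its variance was 20.2, 9.40, 17.3 and 15.7 times that in the Teff pairs and 11.2 times in aTreg pair 4 (lowest 95% limit 5.04), which argues against it as the whole cause there. In aTreg pair 3 it was 0.164 times over 3 clonotypes, and aTreg pairs 1 and 2 had 0 and 1 such clonotypes, so constant spill and shared clones cannot be told apart in these 3 pairs. Cells spilled at a constant rate would need up to 20.2 counts per cell, which the sources do not give, and Tnaive libraries varied by 1.65 to 10.4 times counting error. Spilled cells thus cannot be told apart from clones shared by sorting the same animals.

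For segments, 1 of the 35 splits of 8 libraries gave as many calls as the real one in NEG Teff–Tnaive (51, highest other 0), NEG aTreg–resting Treg (58, highest other 1), resting Treg–Tnaive (83, highest other 0), NEG aTreg–NEG Teff (20, highest other 0) and POS aTreg–POS Teff (3, highest other 0). That is the lowest share that 35 splits can give. This count was also chosen after its results were seen, so it argues against chance there without excluding it. The same held for clonotypes, 1 of the 35 splits each, at 1098, 699, 1323, 550 and 406 calls with a highest other of 0. For POS–NEG aTreg, 4 of the 35 splits gave as many segments (1, highest other 1) and 3 of the 35 as many clonotypes (6, highest other 9), so chance cannot be excluded. Among the 8 of these splits that part every number, the highest other was 0 for segments and for clonotypes. For POS–NEG Teff the real counts were 0 segments (highest other 3) and 0 clonotypes (highest other 13), which 35 of the 35 splits reach whatever the data, so this count decides nothing there, and the 13 calls of another split point to a structure among these libraries. With the block on replicate number, the real arrangement of the 8 that swap cells within numbers gave 59 clonotypes in POS–NEG Teff (highest other 3) and 79 in POS–NEG aTreg (highest other 0). Splits that part every pair and those that do not are mixed in the 35, and 8 arrangements are too few for a share under 0.05.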
